A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

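Total RNA of Saccharomyces cerevisiae, extracted with hot phenol, was sequenced directly as RNA on the Oxford Nanopore platform, a method in which the read starts at the poly(A) tail and therefore marks the 3′ end of the transcript. The 9 libraries form 3 groups of 3 libraries, each treated with rapamycin for 2 h. Per the submitters' processing notes the genome build was R64. The aligner, the tool that assigned reads to genes and their versions are not given in the sources used here.

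The deposited tables hold, for each gene and each 3′ end position, a signal, that is, a scaled number of read ends, in a single column per group in which the 3 libraries are pooled. The scale is not given in the sources used here. All listed values (100%, within 0.001 of a read) were whole multiples of a step of 0.0429 in the WT table, 0.0510 in the Bdp1AA table and 0.0758 in the Bdp1AA Rna15AA table. The step was taken as the signal of 1 read, and read numbers were recovered by division. The recovered totals were 24559388 reads for WT, 16661847 for Bdp1AA and 7740285 for Bdp1AA Rna15AA, counting a read under each gene it is listed for. Between 5.46% and 9.01% of positions were listed under several genes. The WT table and the Bdp1AA Rna15AA table list positions from 11 reads up and the Bdp1AA table from 2 reads up. All tables were therefore set to a common minimum signal of 0.83413 per position, which corresponds to 20 reads in WT, 17 in Bdp1AA and 11 in Bdp1AA Rna15AA. This kept 98.1%, 94.4% and 100% of the signal downstream of genes. Because of these minimums, a gene or position without a value is called not listed and no upper limit is given for it.

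Distances were recomputed from the coordinates as nt past the annotated gene end in the direction of transcription. On the minus strand the deposited 3′ UTR length starts at the high-coordinate edge of the gene, so ends inside genes are listed for that strand alone. The comparisons use ends downstream of genes, 22048431, 14096898 and 7020861 reads in the order above. Of 5835 listed genes with a locus tag in the R64 reference annotation, 5826 had identical coordinates there. Another 339 protein-coding features had no tag in it and are treated as dubious: they are counted and not named. The 275 nuclear tRNA genes were taken from the same annotation.

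The planned tests assumed a count per library. As each group is 1 column, no spread between libraries could be computed, and values with counting intervals replaced the tests, as the plan provided. Programs for replicated counts (edgeR, DESeq2, limma and its camera test) were not used. For each pair of groups, genes with at least 60 reads in both tables were compared. The log2 ratio of downstream signal was centred on the median gene, which subtracts −0.51 for Bdp1AA against WT, −0.34 for Bdp1AA Rna15AA against Bdp1AA and −0.86 for Bdp1AA Rna15AA against WT. A gene was called higher or lower at a 2-fold difference. The shift was the difference in mean 3′ end position, called distal or proximal from 20 nt. Poly(A) site usage joined ends at most 25 nt apart into clusters of at least 10 reads and called a gene where 20 percentage points of its reads sat in other clusters. Genes with a tRNA gene on either strand within 500 bp past their end were set against genes with none within 1000 bp. Ends beyond the tRNA gene were those past its far edge. The profile summed ends in 10 nt bins up to 300 nt on either side of the 5′ edge of each tRNA gene, with −150 to −1 nt as its main window. Intervals of read shares and log2 ratios are exact 95% intervals of the read counts and cover counting error only. Intervals of shares of genes are exact 95% intervals of the gene counts. These treat genes as independent and hold no read-counting error.

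Gene lists were written before the data were examined, as were the comparisons, the distances, the alternatives given below as fixed in advance and the rule for named genes. A list median was compared with 10000 random lists of the same size matched on expression in 10 bins, and its percentile among them is given; lists needed 5 compared genes. A list of transposable element features was added after the data were seen. Named genes are the strain genes BDP1, RNA15, FPR1 and RPL13A, the 10 highest and 10 lowest genes of each comparison, the 10 genes with the largest distal shift and the 5 with the largest proximal shift, the 10 with the largest site usage difference, the 10 largest shifts in either direction among genes with a tRNA gene downstream, and up to 4 members per list. Overlapping genes were named once, by the member with most reads, and 1 gene that the rule names is not reported here.

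The procedure was tested on simulated data in which 200 genes carried a 4-fold change and 200 a 50 nt shift. All groups were drawn from the deposited Bdp1AA ends, with the signal per read and listing minimum of each table and counting error alone. In the 3 comparisons 4831, 4249 and 4259 simulated genes could be compared, against 4543, 2935 and 3003 in the data. Counts without change are therefore not a matched baseline for the depth and end pattern of the double depletion. All of the 4-fold changes that could be compared were recovered (154, 126 and 137 in the 3 comparisons) and between 98.3% and 99.0% of the shifts. Among genes simulated without change, 66 of 4486, 38 of 3949 and 40 of 3946 passed the distal limit of 20 nt.

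Alternatives fixed in advance were median-of-ratios scaling over the 3 tables, the deposited scale without centring, no filter on reads, 30 or 150 reads per gene, the median position, cluster gaps of 10 and 50 nt, clusters of 50 reads, tRNA gene distances of 250 and 1000 bp, separate strands, the near edge of the tRNA gene, the mean of the genes' own shares, a profile window of 300 nt, isolated tRNA genes and removal of noncoding and Ty features. Chosen after seeing the data were the total of listed signal as the scale, the minimum as deposited or doubled, each end counted under the nearest gene alone, protein-coding genes of the reference alone, lists matched on length as well, the separate strands for ends beyond tRNA genes, the median position for genes with a tRNA gene downstream, the shift without noncoding and Ty features, and ends beyond tRNA genes counted in genes with enough reads in both tables or without the gene with most such reads. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sequence reads were not used here.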

Results

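The data are 3′ end positions of yeast transcripts read by direct RNA sequencing after 2 h of rapamycin. In the anchor-away system, rapamycin ties a protein fused to the FRB domain to an FKBP12-tagged anchor, here on the ribosomal protein Rpl13A, and removes it from the nucleus. There were 3 libraries without a tagged target (the group labelled WT, called WT below), 3 in which Bdp1 was tagged (Bdp1AA), and 3 in which Bdp1 and Rna15 were tagged (Bdp1AA Rna15AA, the double depletion). Bdp1 is a subunit of TFIIIB, the factor that places RNA polymerase III (Pol III) at tRNA genes, and Rna15 is a subunit of cleavage factor IA, which acts in mRNA 3′ end formation. After the common minimum, downstream ends amounted to 22048431 reads and 5619 genes in WT, 14096898 reads and 5337 genes in Bdp1AA, and 7020861 reads and 4506 genes in the double depletion. No check against the spread between libraries was possible because the 3 libraries of a group share 1 column. All intervals are 95% counting intervals, of genes for shares of genes and of reads otherwise. Log2 ratios are relative to the median gene, whose signal on the deposited scale differed by −0.51 in Bdp1AA and by −0.86 in the double depletion against WT, and by −0.34 between the depletions.

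The tagged genes were examined first. BDP1 (YNL039W, chromosome XIV, 555048–556832, plus strand) had a downstream signal of 14.6 in WT, from 340 reads, and was not listed under its own name in either depletion table. At position 556828, which is 4 nt before the end of BDP1, ends were listed under the upstream gene YNL040W, with 29 reads in Bdp1AA, 69 in the double depletion and none in WT. RNA15 (YGL044C, chromosome VII, 416146–417036, minus strand) had a downstream signal of 19.8 in WT and of 17.5 in Bdp1AA. In the double depletion no end was listed downstream of RNA15, and a signal of 29.0, from 382 reads, lay inside the gene with its top position 4 nt before the gene end. FPR1 (YNL135C, chromosome XIV, 371882–372226, minus strand) encodes the endogenous rapamycin-binding protein and is given as deleted in the labels of all groups. It had a signal of 6.78 in WT, from 158 reads at its downstream ends, and was not listed in either depletion table, so every direction drawn against WT below is against a group that differs from its label at this gene. RPL13A was not listed in any table.

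The first comparison, Bdp1AA against WT, addresses whether TFIIIB at a downstream tRNA gene bears on where an mRNA ends. Of 90 protein-coding genes with a tRNA gene within 500 bp downstream, 16 had a mean 3′ end at least 20 nt further downstream in Bdp1AA (17.8%, 95% interval 10.5 to 27.3%), against 38 of 4258 genes with no tRNA gene within 1000 bp (0.892%, interval 0.632 to 1.22%). All 16 had the tRNA gene on the opposite strand (16 of 75, 21.3%), so that the genes are convergent, and none of the 15 genes with a tRNA gene on the same strand reached 20 nt (interval 0 to 21.8%, which includes the share of the opposite strand). In ALG13, which encodes a subunit of the enzyme that adds the second sugar in N-glycan synthesis, the mean end lay 29.8 nt past the gene in WT and 176 nt in Bdp1AA. In PCL5, the cyclin that directs degradation of the transcription factor Gcn4, it lay at 59.3 and 89.9 nt.

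The median shift of the 90 genes was 3.02 nt, above all of 10000 random lists matched on expression (percentile 100), while the median of the other genes was −0.22 nt. Percentile 100 was not particular to them. It was also reached by snoRNAs (1.94 nt, 10 of 44 distal), transposable element features (2.15 nt, 29 of 82) and tRNA gene features (7.90 nt, 2 of 10). Stress-induced genes stood at percentile 99.5 (0.73 nt, 0 of 28 distal). The shift of ALG13 (chromosome VII, 411552–412160) was 147 nt, that of CUS2, a U2 snRNA-associated protein gene (XIV, 95223–96080), was 137 nt, that of YOR059C (XV, 438906–440258) was 124 nt and that of YOR289W (XV, 853357–854112) was 112 nt. Smaller distal shifts were those of YMR099C (48.8 nt), MFM1, a mitochondrial magnesium channel gene (41.3 nt), MTC3 (40.5 nt), PCL5 (30.7 nt) and DFG5, a cell wall gene (28.0 nt). PPQ1, a protein phosphatase gene, had a proximal shift of −111 nt, which changed sign with the median position (4 nt) and the doubled minimum (3.30 nt), both short of the 20 nt limit, and became distal with ends counted under the nearest gene (21.1 nt). Among all 4543 genes compared, 106 had a distal and 41 a proximal shift, and the median shift was −0.17 nt. Genes simulated without change gave 66 distal and 66 proximal calls among 4486, and 1 distal call among the 83 of these with a tRNA gene downstream. The distal count was 55 without noncoding and Ty features and 337 at the minimum as deposited, where 23 of 96 genes with a tRNA gene downstream were distal (24.0%) against 5.20% of the others.

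**Figure D1:**
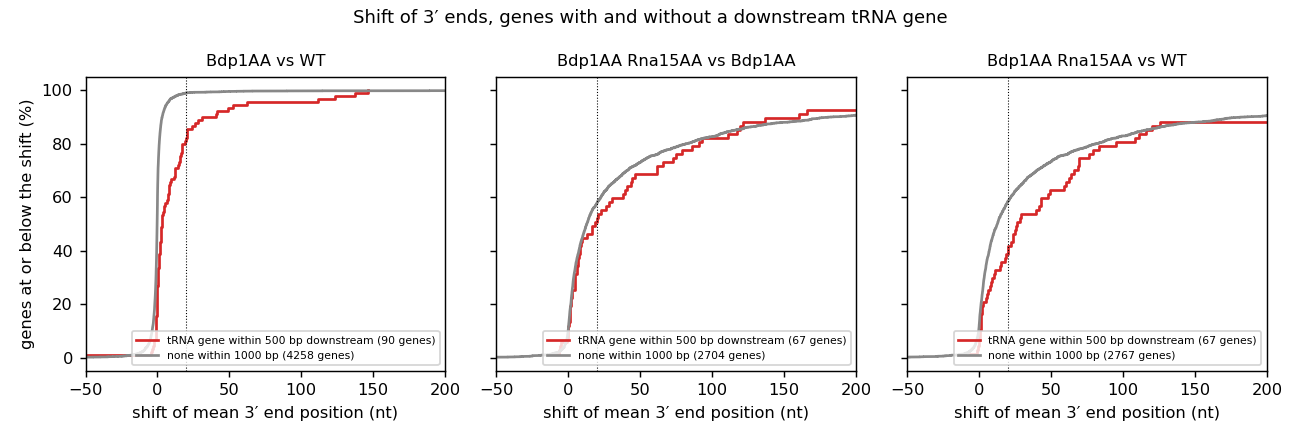
Cumulative share of genes (%) by shift of the mean 3′ end position (nt) for genes with a tRNA gene within 500 bp downstream (red) and genes with none within 1000 bp (grey), in the 3 comparisons; the dotted line marks 20 nt. In Bdp1AA against WT the share past the line is 17.8% of the red and 0.892% of the grey genes, and in the double depletion against Bdp1AA it is 49.3% and 42.2%.

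Ends beyond the far edge of the downstream tRNA gene made up 59 of 290596 reads of the 107 genes listed with a tRNA gene within 500 bp in WT (0.0203%) and 1149 of 208467 reads of 102 such genes in Bdp1AA (0.551%, interval 0.520 to 0.584%). In the 90 genes compared they made up 34 of 286989 reads in WT (0.0118%) and 1082 of 207994 in Bdp1AA (0.520%). PCL5, whose expression was higher in Bdp1AA, supplied 624 of these reads, and without it the shares of the other 89 genes became 0.0119% and 0.230%. With each gene of at least 60 reads weighted equally the shares were 0.0452% and 2.26%. Of the 90 genes, 1 had such ends in WT (PPQ1) and 7 in Bdp1AA (ALG13, YOR059C, YOR289W, CUS2, PCL5, CHO1 and DFG5), named here after their values were seen. In Bdp1AA, 68 of 167 reads of ALG13 ended beyond tV(AAC)G1 (40.7%, interval 33.2 to 48.6%), and none of its 532 WT reads did. The share was 40.7% for YOR059C past tK(UUU)O, 30.4% for YOR289W past tA(UGC)O, 27.1% for CUS2 past tG(UCC)N, 6.87% for PCL5 past tF(GAA)H1, 3.98% for CHO1, the phosphatidylserine synthase gene, past tH(GUG)E1, and 2.67% for DFG5 past tR(UCU)M1. None of the 7 genes had an end listed beyond its tRNA gene in WT. PCL5 had 872 reads in WT against 9088 in Bdp1AA. At its Bdp1AA share, such ends could lie below the common minimum per position in WT. Whether they were absent from WT can therefore not be told for PCL5. For MFM1, YMR099C and MTC3 the more distal ends in Bdp1AA lay before the far edge of the tRNA gene. In coding genes, 2.04% of the signal in WT and 3.93% in Bdp1AA lay more than 500 nt past the gene. As a mean over genes these shares were 2.00% and 1.74%. No share past the same distances as the tRNA genes was computed for genes without one.

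Poly(A) site usage differed by at least 20 percentage points in 69 of 4543 genes (1.52%), against 20 of 4486 genes simulated without change. The most used site differed in 66, being more distal in Bdp1AA in 50. The count of 69 became 195 with clusters joined at 10 nt and 36 at 50 nt. The genes with the largest differences included MFM1 (64.8 percentage points), AVL9, a secretory pathway gene (52.4), RHB1, a small GTPase gene (48.0), HDA1, a histone deacetylase gene (46.4), PRP40, a splicing factor gene (46.0, with a shift of −17.6 nt), MYO1, the type II myosin heavy chain gene (43.9), MTC3 (42.7) and ALG13 (40.7). HDA1 and RHB1 also had distal shifts of 291 and 249.8 nt without a tRNA gene nearby, and NSL1, a kinetochore gene, one of 190 nt that turned to −44.8 nt at the minimum as deposited. Features with near-identical copies or overlapping neighbours gave uncertain shifts. Those of tG(GCC)D2 (583 nt), the ribosomal RNA features RDN58-2 (455 nt) and ITS2-2 (187 nt), and snR60 (234 nt) were distal, as were ETS1-1 (384 nt) and the Ty feature YDR261C-C (180.3 nt), which turned to −12.4 and −19.9 nt with ends counted under the nearest gene. Proximal shifts of YLR112W (−260.5 nt), PRI1, a primase subunit gene (−145 nt), and SLD5, a replication gene (−82.0 nt), likewise turned under an alternative, to 10.8 nt with the nearest gene, 1.16 nt with the doubled minimum and 5.09 nt at the minimum as deposited. That of SNP1, the U1-70K gene (−105 nt), did not turn.

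In expression, genes of amino acid biosynthesis that are targets of Gcn4 stood highest in Bdp1AA. Of 52 compared members of this list, 41 were at least 2-fold higher than in WT and 1 was lower, with a median log2 ratio of 1.90 (percentile 100). ARG1, the argininosuccinate synthetase gene (YOL058W, XV, 219211–220473), had a log2 ratio of 7.50 (interval 7.29 to 7.73), from a signal of 7.38 in WT and 939 in Bdp1AA. ARG3 stood at 5.61, SNZ1, a vitamin B6 gene, at 4.88 and HIS4 at 4.48. The other genes among the 10 highest were YGL117W (6.00), TMT1, a trans-aconitate methyltransferase gene (5.60), ARG4 (4.34), ARG7 (4.25), ARG8 (4.20) and PCL5 (4.14).

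Ribosome biogenesis genes stood low: 24 of 59 were at least 2-fold lower and none higher, with a median of −0.77 (percentile 0.00). Examples were UTP10 (−2.18), RRP12 (−1.64), MAK5 (−1.55) and ERB1 (−1.52). Of 136 ribosomal protein genes, 11 were lower and none higher (median −0.18, percentile 0.00), among them RPL7B (−2.96), RPL42A (−2.86), RPS9A (−2.75), RPS24A (−2.71) and RPL8A (−2.67), each of which has a paralog that can share its reads. Genes for tRNA processing and modification had a median of −0.69 (4 of 21 lower), with the tRNA exporter genes LOS1 at −1.55 and MSN5 at −1.20. Pol III subunit genes had a median of −0.30 (3 of 17 lower and 1 higher), with the large subunits RET1 at −1.85 and RPO31 at −1.53 and the small subunit RPC17 at 1.01. These genes are 3450, 4383 and 486 nt long and follow the length trend given below. As a list, however, Pol III subunit genes stood at percentile 1.61 matched on expression and 0.155 matched on length as well. With length matched too, tRNA processing genes stood at percentile 0.01 and ribosome biogenesis genes at 0.00. Of 8 TFIIIB and TFIIIC genes compared, none differed by 2-fold (median −0.15; SPT15, the TATA-binding protein gene, 0.01). RPR1, the RNase P RNA made by Pol III, stood at −1.15. As reads start at the poly(A) tail, this value covers transcripts with a tail alone. The same holds for the snoRNA, tRNA gene and rRNA features below.

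Stress-induced genes had a median of 0.61 (7 of 28 higher and none lower, percentile 100), led by CYC7 (2.27), TMA10 (1.70), HSP31 (1.56) and HSP12 (1.28). Genes under nitrogen catabolite repression had a median of 0.51, which was 0.00 on the deposited scale. Of 22 compared, 6 were higher, including UGA3 (3.51) and CAR1 (1.62), and 3 lower, including ASP3-1 (−4.35) and DUR1,2 (−1.62). The phosphate regulon had a median of −0.54 (4 of 13 lower), with PHO81 at −1.93, PHO12 at −1.79, PHO11 at −1.65 and VTC3 at −1.55. The NNS termination list had a median of −0.81 over 7 genes, with ADE12 at 1.75 and URA2 at −1.49. Cleavage and polyadenylation factor genes had a median of −0.36 (1 of 21 higher, SYC1 at 1.12), and exosome genes one of −0.21 (1 of 16 lower, MTR4 at −1.54), at percentiles 12.6 and 13.6, within the range of 95% of random lists.

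In several lists no compared member differed by 2-fold. The medians were −0.20 for 26 heat shock and chaperone genes, −0.14 for 19 aminoacyl-tRNA synthetase genes, 0.45 for 11 histone genes, 0.26 for 33 proteasome genes, 0.16 for 7 reference genes including ACT1 (0.16) and 0.02 for 18 glycolysis genes, and the last 4 became −0.06, −0.26, −0.36 and −0.50 on the deposited scale. Translation factor genes had a median of −0.17 (2 of 26 lower, FUN12 and RPG1, both −1.07). The 5 compared DNA damage genes had a median of 0.21, which was −0.30 on the deposited scale, with HUG1 at 1.11. For 44 snoRNAs the median was 0.19, which was −0.33 on the deposited scale, with 4 higher, among them snR17a (2.37) and snR17b (1.94), and 2 lower. Percentiles among lists matched on length as well differed from those matched on expression alone for snoRNAs (0.00 against 97.9), transposable element features (99.7 against 1.55), tRNA gene features (0.00 against 25.8), aminoacyl-tRNA synthetases (68.4 against 1.55), translation factors (16.3 against 0.27) and the NNS list (5.21 against 1.54). The transposable element features, whose copies share reads, had a median of −0.02, which was 0.07 with median-of-ratios scaling, and 3 of 82 were higher and 7 lower. Of 10 tRNA gene features, 4 were lower and 1 higher (median −0.27), the lowest being tK(UUU)D (−3.83). Its ends lay on average 133 nt past the tRNA gene in WT and 145 nt in Bdp1AA. As only ends downstream of a feature are counted, these values are not levels of mature tRNA. Of 4 alpha-specific genes, MF(ALPHA)2 was lower (−1.06). The lists of a-specific, sporulation and mitochondrially encoded genes had no compared member.

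Across the genome, 285 genes were at least 2-fold higher and 452 lower among 4543, so that 38.7% of these genes were higher, against 11.3% on the deposited scale (140 higher and 1098 lower). The counting interval lay beyond 2-fold for 210 higher and 262 lower genes. Apart from the ribosomal protein genes and tK(UUU)D given above, the lowest genes were YFR032C-B (−5.76), ASP3-1 (−4.35), the subtelomeric YHL050C (−2.99) and TRA1 (−2.87). The WT ends of YFR032C-B all lie at positions also listed for a neighbour. ASP3-1, of the nitrogen catabolite repression list, is an asparaginase gene with identical copies, and TRA1 encodes a subunit of the SAGA and NuA4 complexes. Longer genes were lower: the median log2 ratio was 0.51 in the shortest sixth of coding genes and −0.87 in the longest, with a rank correlation of −0.64 across 4338 genes, which are not independent replicates. Ratios of low long genes named above, such as UTP10 (5310 nt) and URA2 (6645 nt), cannot be told apart from this trend. The same holds for high short genes such as HSP12 (330 nt). Others went against the trend, such as RPL42A (833 nt, −2.86).

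The second comparison, the double depletion against Bdp1AA, asks what loss of nuclear Rna15 adds. Of 2935 genes compared, 1238 had a mean 3′ end at least 20 nt further downstream (42.2%) and 37 further upstream, and 522 lay at least 100 nt further downstream. COX19, a gene for cytochrome c oxidase assembly, had a shift of 2624 nt and FIS1, a mitochondrial fission gene, one of 2428 nt. At PTA1, which encodes a subunit of the cleavage and polyadenylation factor, all 97 reads of the double depletion ended at other sites than in Bdp1AA, with a shift of 752 nt.

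The median shift was 12.6 nt, with quartiles of 2.62 and 57.7 nt, and 38 distal and 41 proximal calls arose among 3949 genes simulated without change. The distal count was 640 with the median position. Other genes with the largest distal shifts were NPL4, a Cdc48 cofactor gene (2427 nt), FUN26, a nucleoside transporter gene (2160 nt), YMR310C (2086 nt), PMT1, a protein mannosyltransferase gene (1902 nt), PAN6 and MDM38 (both 1889 nt) and CAB4 (1837 nt). The proximal calls named by rule were all in RNA genes: RDN58-2 (−634.5 nt), ITS2-2 (−534 nt), ETS1-1 (−264 nt, but 51.6 nt with ends counted under the nearest gene), RDN5-5 (−111 nt) and snR68 (−104 nt). Site usage differed by at least 20 percentage points in 765 genes (26.1%), against 33 of 3949 simulated without change, and the most used site differed in 393, being more distal in 375. The difference was 100 percentage points in PTA1, MST28, RER2, ADH5, NPL4, VBA2, TFB3, YEA6, YND1 and YER134C. Of the coding signal, 3.93% in Bdp1AA and 4.96% in the double depletion lay more than 500 nt past the gene, or 1.74% and 6.38% as a mean over genes. The number of coding genes with ends also listed for an upstream gene on the same strand was 96 in Bdp1AA and 669 in the double depletion.

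Of the genes with a tRNA gene downstream, 33 of 67 were distal in this comparison (49.3%), with an interval of 36.8 to 61.8% that includes the 42.2% of the other genes, and their median shift of 18.5 nt stood at percentile 86.6 of random lists. With the median position the shares were 19.4% and 22.3%. The ends beyond the tRNA gene made up 3342 of 154040 reads in the double depletion (2.17%, interval 2.10 to 2.24%) against 0.551% in Bdp1AA, or 10.6% against 2.26% with genes weighted equally. In the 67 genes compared the shares were 2.17% and 0.493%, and without PCL5 1.71% and 0.191%. Of 67 genes with enough reads in all 3 tables, 31 had such ends in the double depletion, 5 in Bdp1AA and 1 in WT. The share was 75.0% for PCL5, 79.2% for CHO1, 91.8% for YOR059C, 100% for YOR289W and 43.3% for CUS2, and ALG13 was not listed. ERF2, a palmitoyltransferase subunit gene whose tRNA gene tL(CAA)L lies on the same strand, had a share of 82.8% and none in Bdp1AA. Shifts against Bdp1AA were 337 nt for PCL5, 331 nt for ERF2, 300.2 nt for CHO1, 247 nt for YOR289W, 211 nt for MFM1, 166 nt for YMR099C, 160.3 nt for YOR059C, 137 nt for PPQ1, 121 nt for YDR391C and 119 nt for AVT7. Whether the rise in ends beyond the tRNA gene exceeds the general distal shift cannot be told. No share past the same distances was computed for genes without a tRNA gene.

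**Figure D2:**
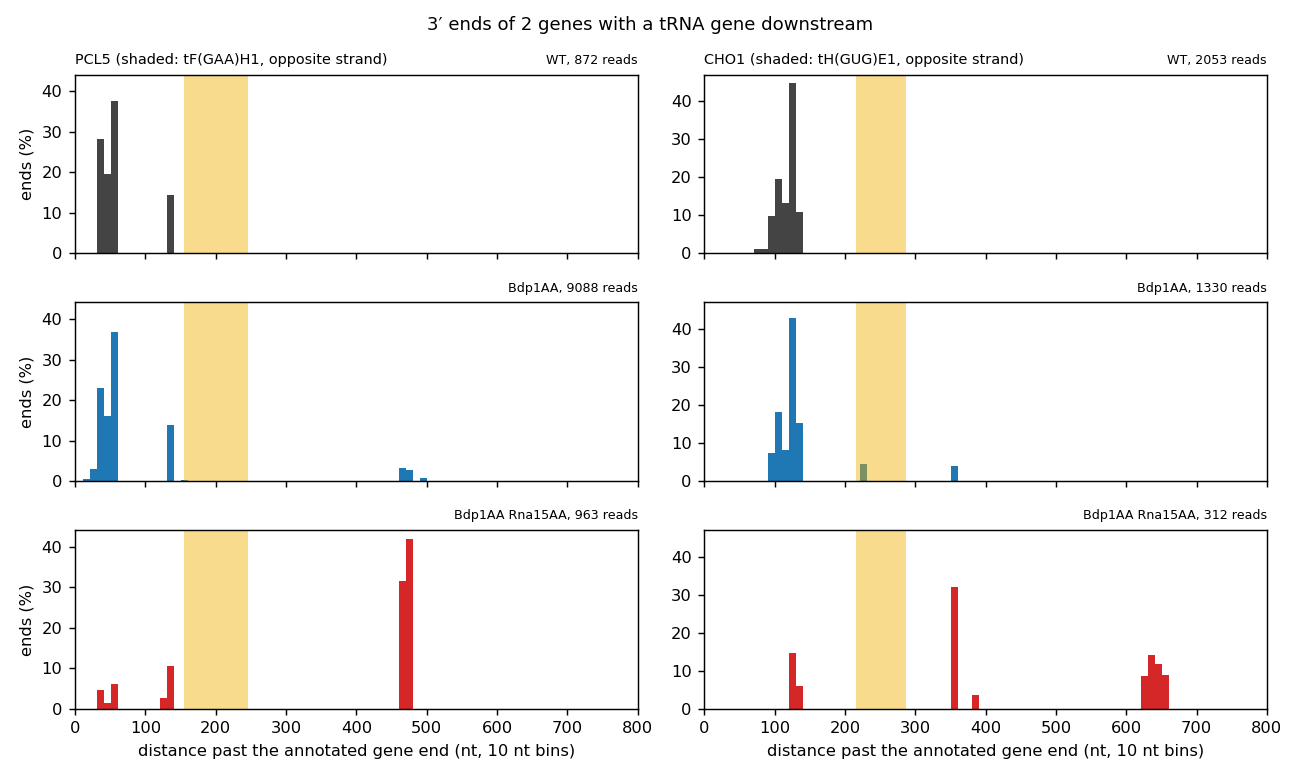
Share of a gene's 3′ ends (%) per 10 nt bin of distance past the annotated gene end (nt) for PCL5 and CHO1 in WT, Bdp1AA and the double depletion; shading marks the tRNA gene on the opposite strand. Ends beyond the shading make up 0%, 6.87% and 75.0% of listed PCL5 reads and 0%, 3.98% and 79.2% of listed CHO1 reads. PCL5 has 872 reads in WT and 9088 in Bdp1AA, and CHO1 2053 and 1330. The 0% of PCL5 in WT does not show absence, since such ends could lie below the common minimum per position.

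In expression, the Gcn4 target list that stood highest in Bdp1AA was lower in the double depletion: 30 of 46 compared members were at least 2-fold lower than in Bdp1AA and 3 higher, with a median of −1.73 (percentile 0.00). ARG8 stood at −5.07, ARO3 at −3.93, LEU4 at −3.41 and TRP4 at −3.34. Ribosomal protein genes had a median of −0.60 (40 of 136 lower and 2 higher, percentile 0.00), with RPL26A at −3.84 and RPL36A at −3.08. Histone genes had a median of −0.99 (4 of 9 lower), with HTB2 at −4.89, but at percentile 3.2 the list lay within the range of 95% of random lists.

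Stress-induced genes were higher, with a median of 1.13 (14 of 25 higher and 3 lower, percentile 99.9), led by HSP12 (5.26), DDR2 (3.87) and ALD4 (3.44). Of 81 transposable element features, 70 were higher and none lower (median 1.20, percentile 100). Genes under nitrogen catabolite repression had a median of 1.46 (6 of 12 higher and 2 lower), including DAL80 (3.45), PUT2 (2.74) and the ammonium permease gene MEP2 (2.28). For 31 snoRNAs the median was 0.84 (13 higher and 4 lower). Among 33 proteasome genes 14 were higher and 6 lower (median 0.42, percentile 88.0), with RPN4, the transcription factor of these genes, at 3.26, RPN1 at 3.24 and PRE4 at 2.73. The median shift of the proteasome list was 48.8 nt (percentile 99.5), with 23 of 33 genes distal. Ribosome biogenesis genes had a median of 0.38 (13 of 47 higher and 6 lower), heat shock and chaperone genes one of 0.48 (5 of 25 higher and 3 lower; MDJ1 2.64, STI1 −1.48) and glycolysis genes one of 0.37 (4 of 18 higher; PDC5 3.69, PGK1 2.05). At percentiles 92.7, 92.1 and 89.4 these lists, like the proteasome list, lay within the range of 95% of random lists in expression.

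The lists that follow lay within that range too when matched on expression, and of them only the aminoacyl-tRNA synthetases lay outside it when matched on length as well (percentile 1.5 against 32.0). Cleavage and polyadenylation factor genes had a median of 0.45, with RNA14, whose product pairs with Rna15, at 2.01, REF2 at 1.98 and HRP1 at 1.34 among 3 of 11 higher, and PAB1 lower at −2.83. In the NNS list (median 0.51 over 6 genes), IMD2 stood at 2.61 and NRD1 at 1.26 with a shift of 480 nt. Aminoacyl-tRNA synthetase genes had a median of −0.20, which was 0.19 with median-of-ratios scaling, with 7 of 18 lower, among them DPS1 (−4.28), whose ends lay 692 nt further downstream. Medians were −0.41 for exosome genes (4 of 11 lower; RRP42 −2.85 from downstream ends, while 59.5% of its 200 reads in the double depletion ended inside the gene), −0.70 for the phosphate regulon (5 of 13 lower and 4 higher; PHO3 −3.54), and −0.39 for Pol III subunit genes (2 of 11 lower and 1 higher), the last being 0.00 with median-of-ratios scaling. Translation factor genes had a median of −0.02, which was 0.37 with median-of-ratios scaling, with SUI1 at 2.77 and TIF35 at −2.39. On the deposited scale the medians of tRNA processing genes (0.18) and reference genes (0.23) became −0.16 and −0.10. BRF1, the TFIIIB subunit gene, stood at 1.03, and 5 tRNA gene features had a median of 0.44.

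The 10 highest genes were MUD1, a U1 snRNP gene (6.26), YJL047C-A (6.20), which overlaps snR60, MGR1 (5.67), HSP12, the pyruvate carboxylase gene PYC1 (4.79), the zinc transporter gene ZRT1 (4.58), YOL036W (4.48), SNZ3 (4.24), PSH1 (4.24) and MAM33 (3.96). Part of the signal of 3 of them lay at positions also listed for an upstream gene: 43.6% for MUD1, 32.1% for MGR1 and 20.1% for YOL036W. The 10 lowest genes were BNA1 of the kynurenine pathway (−6.30, interval −6.68 to −5.94), PDX3 (−5.51), SOL3 (−5.25), RIB4 of riboflavin synthesis (−5.12), YOR385W (−5.10), ARG8, FUR1, the uracil phosphoribosyltransferase gene (−4.94), HTB2, DIA1 (−4.65) and ERP1 (−4.59). In all, 733 genes were higher and 740 lower, so that 49.8% of these were higher, against 64.8% with median-of-ratios scaling and 34.0% on the deposited scale. The counting interval lay beyond 2-fold for 603 higher and 644 lower genes, and 714 further genes passed the read limit in Bdp1AA and were not listed in the double depletion.

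**Figure D3:**
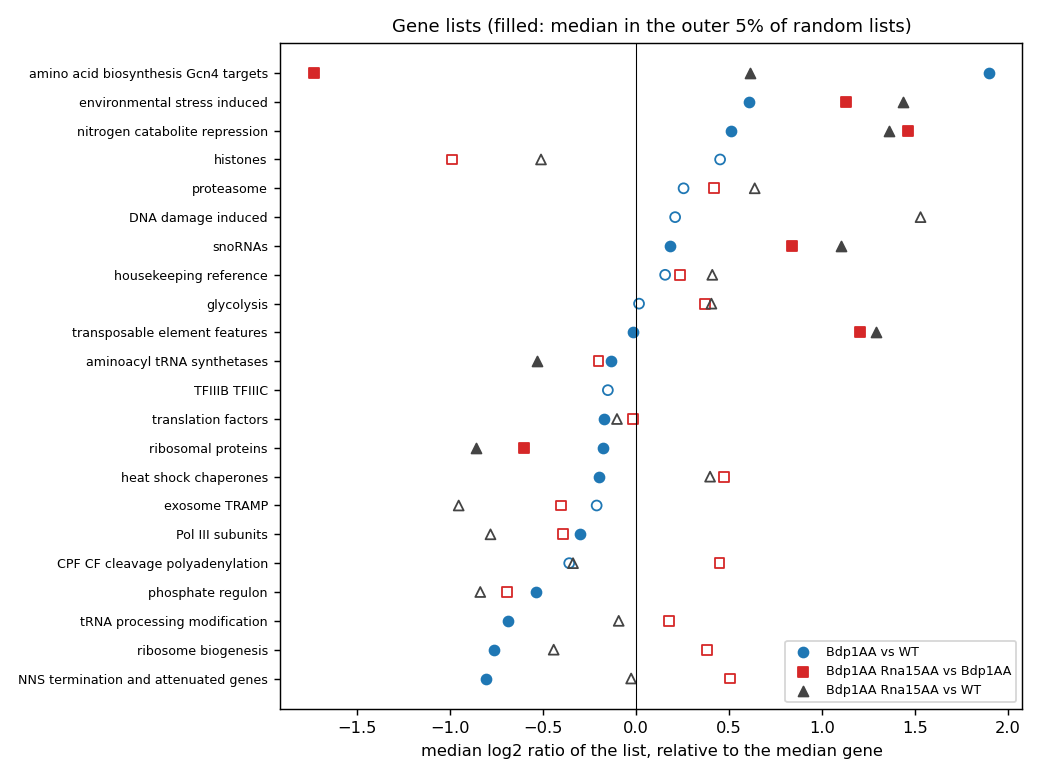
Median log2 ratio of each gene list relative to the median gene, for the 3 comparisons; filled symbols lie outside the range of 95% of random lists matched on expression but not on gene length. The Gcn4 target list stands at 1.90 in Bdp1AA against WT, at −1.73 in the double depletion against Bdp1AA and at 0.61 in the double depletion against WT, the last being −0.24 on the deposited scale.

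The third comparison, the double depletion against WT, gives the combined difference. Genes with a tRNA gene downstream were distal more often than others here: 40 of 67 (59.7%, interval 47.0 to 71.5%) against 41.5%, with a median shift of 26.3 nt (percentile 98.0) against 12.6 nt. With the doubled minimum the difference was smaller, 44.3% (interval 31.5 to 57.6%) against 34.7%, and the interval included the share of the other genes. With the tRNA gene on the opposite strand 37 of 56 were distal (66.1%), and on the same strand 3 of 11 (27.3%). PCL5 had a shift of 368 nt, YOR289W one of 359 nt, ERF2 one of 338 nt and CHO1 one of 317 nt. The share of ends beyond the tRNA gene was 2.17% against 0.0203% in WT, again without a share past the same distances in other genes.

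Further shifts at these loci were 284 nt for YOR059C, 253 nt for MFM1, 214 nt for YMR099C, 210.2 nt for CUS2, 126 nt for YDR391C and 119.8 nt for AVT7. With the median position the shares of distal genes were 32.8% (interval 21.8 to 45.4%) with and 22.5% without a tRNA gene. Among all 3003 genes, 1259 were distal (41.9%) and 35 proximal, the median shift was 12.9 nt, and 669 genes were distal with the median position. Large distal shifts were those of COX19 (2661 nt), NPL4 (2431 nt), FIS1 (2427 nt), FUN26 (2159 nt), YMR310C (2087 nt), YNL040W (1926 nt), PMT1 (1900.2 nt), PAN6 (1891 nt) and MDM38 (1887 nt). The only position listed for YNL040W in the double depletion is the one 4 nt before the end of BDP1. Proximal shifts named by rule were those of ITS2-2 (−347 nt), RDN58-1 (−180.2 nt, but 25.1 nt with ends counted under the nearest gene), snR78 (−65.6 nt), YDL157C (−62.2 nt) and GLO3, an ARF GTPase-activating protein gene (−57.6 nt). Site usage differed in 791 genes (26.3%), against 25 of 3946 simulated without change, and the most used site was another one in 407, more distal in 391. The difference was 100 percentage points in PTA1, MST28, the histone regulator gene HIR1, RER2, NPL4, VBA2, RHB1, TFB3, YEA6 and YND1.

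Stress-induced genes (median 1.44, 15 of 26 higher and 2 lower) and transposable element features (median 1.29, 55 of 82 higher and 1 lower) stood high against WT, both at percentile 100. HSP12, a membrane stress protein gene, had the largest ratio, 6.55 (interval 6.43 to 6.67), followed by the purine synthesis gene ADE17 (6.33), MUD1 (6.12), snR82 (5.60), snR60 (5.45), ZRT1 (5.13), DDR2 (5.02), the carbonic anhydrase gene NCE103 (4.96), MGR1 (4.94) and USE1 (4.85), whose signal lay to 67.3% at positions also listed for snR82. For 35 snoRNAs the median was 1.10 (19 higher and 2 lower). The nitrogen catabolite repression list had a median of 1.36, with 6 of 12 higher and 2 lower, the 5 DNA damage genes one of 1.53, with RNR4 (2.38), RAD54 (1.85) and HUG1 (1.53) higher, and 5 tRNA gene features one of 1.87. The DNA damage list stood at percentile 96.2, and the tRNA gene features at 98.5, which was 83.5 among lists matched on length as well. Of the Gcn4 targets 16 of 46 were higher and 6 lower (median 0.61, but −0.24 on the deposited scale), with SNZ1 at 4.77, LYS1 at 4.70, ARG1 at 4.39 and SER3 at 3.85. Proteasome genes had a median of 0.64 (14 of 33 higher and 5 lower), glycolysis genes one of 0.41, reference genes one of 0.41 and heat shock genes one of 0.40, which on the deposited scale became −0.22, −0.45, −0.44 and −0.46, and all 4 lay within the range of 95% of random lists.

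Ribosomal protein genes stood low, with 61 of 136 lower and 1 higher (median −0.86, percentile 0.00), among them RPL8A (−5.17), RPL26A (−4.30) and RPL7B (−3.96). Aminoacyl-tRNA synthetase genes had a median of −0.53 (5 of 18 lower, percentile 1.47). Medians within the range of 95% of random lists were those of exosome genes (−0.95, 4 of 11 lower, percentile 12.6), the phosphate regulon (−0.84, 5 of 13 lower, percentile 7.3), Pol III subunit genes (−0.78, 4 of 11 lower and 1 higher, percentile 5.80) and histone genes (−0.51, 2 of 9 lower and 2 higher, percentile 18.6). Ribosome biogenesis genes (−0.44, 18 of 47 lower and 7 higher, percentile 2.54, or 1.89 matched on length as well), cleavage and polyadenylation factor genes (−0.34), translation factor genes (−0.10), tRNA processing genes (−0.09) and the NNS list (−0.03) had negative medians, within that range when matched on expression, that became 0.03, 0.13, 0.37, 0.38 and 0.45 with median-of-ratios scaling. The lowest genes were ASP3-3 (−6.12), RPL8A, FUR1 (−5.06), YOR385W (−4.79), HTB2 (−4.54), APT1, an adenine phosphoribosyltransferase gene (−4.54), SOL3 (−4.48), YNL010W (−4.31), RPL26A and DIA1 (−4.25). In all, 783 genes were higher and 740 lower, so that 51.4% of these were higher, against 70.2% with median-of-ratios scaling and 18.7% on the deposited scale. The counting interval lay beyond 2-fold for 668 higher and 605 lower genes. These counts leave out 1103 genes that passed the read limit in WT and were not listed in the double depletion, against 81 the other way.

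Around the nuclear tRNA genes, ends of transcripts running against the tRNA gene were summed upstream of its 5′ edge, the side where TFIIIB binds and which a transcript that starts on the other side reaches after crossing the tRNA gene. Where these transcripts start was not examined. Few loci supplied it. From −150 to −1 nt this signal was 7.80 in Bdp1AA, from 2 tRNA genes with 65.4% at tK(UUU)O, and 39.1 in the double depletion, from 8 tRNA genes with 41.5% at tK(UUU)O, and no such end was listed in WT. In the wider window from −300 nt the signal was 0.987 in WT, 111 in Bdp1AA, from 8 tRNA genes with 49.3% at tG(GCC)E, and 186 in the double depletion, from 23 tRNA genes with 29.0% at tF(GAA)H1. Transcripts running in the direction of the tRNA gene had a signal of 827 in WT, 556 in Bdp1AA and 1620 in the double depletion from −150 to −1 nt. Within −50 to −1 nt, a window chosen after the profile was seen, no such end was listed in WT, and the signal was 2.80 in Bdp1AA and 199.9 in the double depletion, 68.4% of it at tS(AGA)E.

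**Figure D4:**
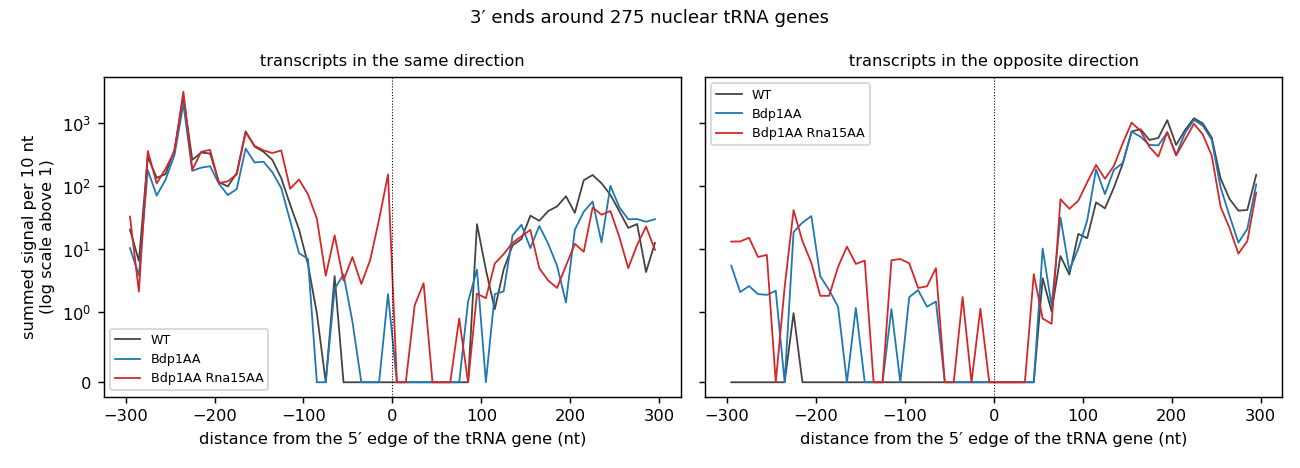
Summed 3′ end signal per 10 nt bin by distance (nt) from the 5′ edge of the nuclear tRNA genes, for transcripts running with and against the tRNA gene, on a symmetric log axis that is linear near 0. Against the tRNA gene, the signal from −150 to −1 nt is 0 in WT, 7.80 in Bdp1AA and 39.1 in the double depletion.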

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

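Of the tests below, those on genes without a tRNA gene downstream, on the longest genes with positions as deposited, on introns, on shared positions and on the listing of features in the depletion tables were chosen after the result was seen, and the redraws of the Bdp1AA ends were added after those of the WT ends had been seen.

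Ends inside genes lie outside the comparisons above because the tables list them on the minus strand alone. They made up 17.9% of the Bdp1AA signal on that strand and 15.9% in the double depletion, shares above the 15.4% of the control group WT in data the comparisons do not use. The signal itself was not above WT, at 87397 in WT, 86113 in Bdp1AA and 54554 in the double depletion. Of 1378 genes the share was at least 20 percentage points higher than in WT in 1 gene and lower in 8 in Bdp1AA, and higher in 6 and lower in 10 in the double depletion. Ends inside RNA15 had a signal of 29.0 in the double depletion and were not listed in WT, a difference from the control group at a tagged gene.

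In Bdp1AA, 16 genes with a tRNA gene downstream had ends at least 20 nt further downstream than in WT. Depth and the listing minimum of the Bdp1AA table alone are argued against by 20 redraws of the listed WT ends at the Bdp1AA totals, which gave at most 1 such gene (mean 0.45). Distal WT ends hidden by the minimum of the WT table are argued against as the source of all 16. In 20 redraws of the Bdp1AA ends at the WT totals and minimum, up to 4 such genes arose (mean 1.9). This is not below the limit of 4 set for excluding hidden ends, so they stay open as the source of some of the 16. A distal shift of protein-coding genes in general is argued against by the 0.892% of those without a tRNA gene that shifted. This does not extend to snoRNA and transposable element features, of which 10 of 44 and 29 of 82 shifted. Differing assignment of reads to genes is argued against by the 14 of the 16 genes that still shifted with each end counted under the nearest gene. A difference between the strains other than the tagged gene stays open, since FPR1 ends were listed in WT against its label and strain and group coincide, as does a block to transcription by TFIIIB that its depletion relieves, a hypothesis that no value here tests directly.

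Longer genes were lower in Bdp1AA than in WT, with a rank correlation of −0.64 across 4338 coding genes. The listing minimum is argued against by the longest sixth of genes, which stood at −0.77 with positions as deposited, and short genes of the lists by the correlation of −0.70 across the 3789 genes in no list. Whether reads were assigned by the part of the gene they cover, introns included, cannot be told apart from a difference in RNA: ribosomal protein genes with an intron stood −0.13 from those without, between the values that would decide, and the 153 other genes with an intron had a median of 0.26. A difference in RNA length between the pooled libraries and a biological difference between the groups stay open and were not tested.

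A set of 32 features had at least 600 reads in WT and was at least 16-fold lower or not listed in both depletion tables, among them the 4 ASP3 copies, tRNA genes and the long genes MDN1, URB1 and TOM1. Of the 16 features with reads mostly at positions not listed for another gene, 13 had an end listed in at least 1 depletion table. For ASP3-1 the signal was 593 in WT, 20.3 in Bdp1AA and 4.70 in the double depletion, and its near-identical copies are not independent of it. The ASP3-1 values in the depletion tables rest on 399 reads in Bdp1AA and 62 in the double depletion. Some other signals lay near the common minimum, such as TOM1 with 0.866 in Bdp1AA and tK(UUU)D with 0.834 in the double depletion. Signals as small as these 2 do not decide whether a strain difference removed the loci concerned from both depletion strains. Such a strain difference cannot be told apart from low expression for the other 3 (OSW2, NDT80 and tR(ACG)D), for which neither depletion table lists an end. Neighbouring transcripts counted under an overlapping feature in the WT table stay open as a possible explanation for the rest, since 66.2% of the WT signal of the set lay at positions also listed for another gene and 16 features had at least 90% of theirs there. No biological explanation was tested.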

How the results depend on the processing

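The tests chosen after the data were seen are those with the minimum as deposited or doubled, the nearest gene, coding genes alone, the total of listed signal, lists matched on length, the strands for ends beyond tRNA genes, the median position for genes with a tRNA gene, the shift without noncoding features, and ends beyond tRNA genes in genes with enough reads in both tables or without PCL5. Of 140 alternative values of the main results, 91 were called the same and 49 differed. For counts the call used the size of the total alone, and totals as far apart as 1105 and 737 were called the same. Direction was not checked for counts. On the deposited scale the double depletion against WT was called the same (1690 against 1523), though 316 genes were higher against 783. The cause was not tested for any value below unless its construction gives it. The share of distal genes with a tRNA gene downstream in Bdp1AA against WT lay between 12.2% and 24.6% under the alternatives other than the same strand. For single genes and lists, 2194 values kept their size, 1261 differed in size and 15 reversed, where reversed means a change of sign in a value past its limit (2-fold, 20 nt, or for lists the range of 95% of random lists). Of the list medians 399 of 474 kept their size. A further 29 values of list medians changed sign in lists within that range, 11 of them on the deposited scale and 9 with median-of-ratios scaling, as did 14 log2 ratios short of 2-fold.

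Scaling to the deposited values gave 1238 genes past 2-fold in Bdp1AA against WT, and no filter on reads gave 2437 in the double depletion against Bdp1AA and 2485 against WT, as more genes enter. Distal genes in Bdp1AA against WT numbered 55 without noncoding features, 52 among coding genes, 61 with the median position, 337 at the minimum as deposited and 60 with the nearest gene. The median position gave 640 distal genes in the double depletion against Bdp1AA and 669 against WT, and shares of 19.4% and 32.8% for genes with a tRNA gene, against 22.3% and 22.5% of others. Site usage in Bdp1AA against WT gave 195 genes with a gap of 10 nt and 36 with a gap of 50 nt. The same strand gave distal shares of 0% in Bdp1AA against WT and 27.3% in each comparison of the double depletion, and the doubled minimum 32.3% against Bdp1AA and 44.3% against WT, where other genes had 35.1% and 34.7%.

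The difference in ends beyond the tRNA gene is given in percentage points for Bdp1AA against WT, the double depletion against Bdp1AA and the double depletion against WT, where the values were 0.531, 1.62 and 2.15. It was 1.53, 3.00 and 4.53 within 250 bp, 0.459, 1.44 and 1.90 within 1000 bp, 0.0686, 0.132 and 0.201 on the same strand, and 0.697, 2.51 and 3.21 on the opposite strand. As a mean over genes it was 2.22, 8.35 and 10.6, with the doubled minimum 0.439, 1.25 and 1.68, with the nearest gene 0.495, 1.53 and 2.03, and without PCL5, the gene with most such reads, 0.243, 1.45 and 1.69. Past the near edge it was 0.605 in Bdp1AA against WT, and at the minimum as deposited 0.913 in that comparison and 1.23 in the double depletion against Bdp1AA. The Bdp1AA profile signal of 7.80 against the tRNA gene was 111 in the 300 nt window, 17.0 at the minimum as deposited and 3.97 with the doubled minimum.

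The reversed values in Bdp1AA against WT were the medians of transposable element features (0.0734 with median-of-ratios scaling and 0.0255 with the doubled minimum) and of snoRNAs (−0.33 on the deposited scale), and the shifts of PPQ1 (4 nt with the median position, 3.30 nt with the doubled minimum and 21.1 nt with the nearest gene), NSL1 (−44.8 nt) and SLD5 (5.09 nt) at the minimum as deposited, PRI1 (1.16 nt) with the doubled minimum, and ETS1-1 (−12.4 nt), YDR261C-C (−19.9 nt) and YLR112W (10.8 nt) with the nearest gene. With the nearest gene ETS1-1 also reversed in the double depletion against Bdp1AA (51.6 nt) and RDN58-1 against WT (25.1 nt). The median of the Gcn4 targets in the double depletion against WT reversed on the deposited scale (−0.242).

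No paired analysis was possible because the libraries of a group share 1 column. For the same reason the alternatives of the plan that need single libraries were not run: the DESeq2 and edgeR tests, a fit of only the groups compared, the replicate block, leaving out each replicate and an estimated correlation for the lists. Positions seen in 1 read are absent from the tables, and the 20 nt limit became the main rule. Depth limits the double depletion most, in which the common minimum corresponds to 11 reads and 714 genes compared in Bdp1AA were not listed.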

Other observations

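The values in this part were chosen after the tables were seen and belong to no test, except that TOR1 and the marker genes were on a list fixed in advance.

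Signal outside coding genes lay among others in transposable element, rRNA and snoRNA features. Transposable element features, whose near-identical copies share reads, had a signal of 18226 in WT, 12627 in Bdp1AA and 23420 in the double depletion on the deposited scale, rRNA features 7544, 10005 and 6425, and snoRNAs 9346, 5794 and 5140. In the double depletion the ends of snR82 lay on average 1159 nt past the gene, against 70.7 nt in WT, and those of snR60 lay 453 nt against 109 nt, so that USE1 downstream of snR82 had 67.3% of its signal at positions shared with it. The ends of snR8 lay 96.8 nt further downstream than in WT and those of snR56 166 nt. In the double depletion against WT, snoRNAs as a list were not distal more often, with 12 of 35 against 41.9% of all genes. Their median shift there stood at percentile 52.4. In Bdp1AA against WT they were, with 10 of 44 against 2.33% of all genes and a median shift at percentile 100.

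Several genes used in strain construction also differed between the groups. Of 7 compared in Bdp1AA against WT, 4 were at least 2-fold higher and none lower, with a median of 1.08 (percentile 99.99). TOR1, the kinase gene whose mutation makes anchor-away strains resistant to rapamycin, had a downstream signal of 14.9 in WT, 2.55 in Bdp1AA and 1.67 in the double depletion. The depletion values rest on 50 and 22 reads. TOR1 (X, 559416–566828) has the length of the longest sixth of coding genes, whose median was −0.87 in Bdp1AA against WT. Its difference from WT in Bdp1AA cannot be told apart from that trend. HIS3 stood at 11.5, 91.7 and 1.59, LEU2 at 175, 277 and 10.9, URA3 at 80.2, 65.0 and 16.1, and ADE2 at 7.43, 12.6 and 21.7. TRP1 stood at 164, 164 and 76.7, and CAN1 at 16.9, 28.6 and 11.3. For HIS3 the top position in the double depletion lay 2838 nt past the gene. Of 6 alpha-specific genes on the list, 4 could be compared between Bdp1AA and WT and 2 between the double depletion and WT, while none of 7 a-specific genes could be compared.

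On the minus strand, ends inside RNA15 made up 100% of its reads in the double depletion, 65.3% of those of PBN1 and 59.5% of those of RRP42, none of which had such ends in WT. The transporter genes ENA1 and ENA2 had 18.8% and 19.1% in WT, 34.5% each in Bdp1AA and 53.3% and 54.4% in the double depletion. Other genes had such ends in WT alone, among them SUE1 (79.0%), GCV1 (41.9%) and NTG1 (37.6%).

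The relation of log2 ratio to gene length differed between comparisons. The rank correlation across coding genes was 0.26 in the double depletion against Bdp1AA, with medians of −0.68 in the shortest and 0.50 in the longest sixth, and 0.03 in the double depletion against WT. Of 220 genes at least 4-fold higher in the double depletion than in Bdp1AA, 1 had at least 50% of its signal at positions also listed for an upstream gene.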
